A study of Homo sapiens with 30 samples.

How the data were processed

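Gene expression was measured on 30 bead arrays with RNA from cells labelled MCF-10A, an established line of non-transformed human breast epithelium. Per the labels, every culture overexpressed cyclin E and carried a stable short hairpin RNA (shRNA), and cells were harvested after 48 hours of culture. There were 5 shRNAs (shControl, shATM, shATR, shCHK1 and shCHK2) in 2 sets with 3 replicates each, which makes 10 groups of 3 arrays. The labels do not say what separates the sets, nor whether replicates were separate cultures, so all p-values and standard errors (SE) measure the spread between arrays of a group.

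The deposited table without normalization holds a linear intensity per probe and array, with no background subtracted. Beside each intensity, per the file headers, stands a detection p-value that falls as the probe gets brighter. The authors also gave log2 values, which were quantile normalized over the 30 arrays. Each of their columns had a median of 6.88, and each correlated with the log2 intensity of its own array at r = 0.998 or above across probes. The table has 47231 probes, of which 30113 matched a single gene symbol in the annotation at hand, 8 matched several and 17110 matched none. Genes that matched no symbol were not analysed here by name.

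Intensities were background corrected and quantile normalized with the neqc function of limma (version 3.58.1, R 4.3.3), with the level of the negative controls inferred from the detection p-values and an offset of 16. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which left 26967 probes. Each gene was represented by its kept probe with the highest mean over all arrays, which gave 13721 genes. A gene was counted as detected on an array when any of its probes had a detection p under 0.05. The number of arrays limits the precision. Between 18984 and 21732 probes were detected per array, and signal over background lay between 16 and 23.5.

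A linear model with a mean for each of the 10 groups was fitted with limma, with 20 residual degrees of freedom, and p-values (two-sided) were adjusted by the Benjamini-Hochberg method over all genes. A gene was called changed by a knockdown when its adjusted p was under 0.05 in each set, in the same direction, against shControl of that set. The average over sets, the difference between sets, the contrast of shATR and shCHK1 against shATM and shCHK2, and the contrast between the shControl sets came from the same model. Comparisons of each knockdown with the mean of the other 3 knockdowns, and of knockdown set 2 with knockdown set 1, were added after the data had been seen.

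Before the data were examined, 26 gene lists with 710 entries (612 tested) were fixed. They cover checkpoint signalling, DNA replication, homologous recombination and fork protection, E2F regulators of G1/S, G2 and mitosis, histones, p53 targets, the integrated stress response and unfolded protein response, interferon response, MHC class I antigen presentation, inflammatory cytokines and NF-kB targets, NRF2 and oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, the ERK pathway and immediate early genes, TGF-beta and YAP targets, basal epithelial, luminal epithelial, breast stem and progenitor, keratinocyte differentiation, epithelial junctions, mesenchymal and extracellular matrix, and markers of leukocytes and of endothelial cells and fibroblasts. Lists were tested with limma's camera on the average over sets, with a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation. Member counts use the calls in both sets, and stand beside counts adjusted over the list alone.

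The genes named in the text were chosen by a rule fixed beforehand. It takes the 4 targets and CCNE1, the 8 genes that rose and the 8 that fell most per knockdown, the 6 per direction with the largest smallest change for all 4 knockdowns and for the contrast of kinase pairs, and up to 4 members of each list described. Where the compared probe was detected on none or a minority of the arrays of the dimmer side, the fold is a lower bound, with those arrays set no lower than their dimmest detected probe. That rule was widened from none to a minority after the data had been seen.

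The overlap of the 4 knockdowns was set beside 20 simulations of unchanged groups that share the controls, the overlap of independent lists, and a fit in which the controls were split between knockdowns. The procedure was tested on simulated data with 13489 unchanged genes. None of these was called in both sets and 8 were called on the average, while 38% of genes changed 1.5-fold and 90% of genes changed 2-fold were called in both sets. The simulated arrays varied independently, with no difference between sets. The measured arrays of a group correlated at 0.571, and the sets differed, so these rates need not hold for them. Alternatives covered the authors' log2 values, no background correction, median scaling, filters, the mean over probes, array weights, replicate terms, a minimum of 1.5-fold, tests within a set and leaving out each array. Added after seeing the data were a fit without 2 arrays that stand apart and a fit with chromosome medians subtracted. Counts were also recomputed over 100 random splits of the arrays, or over all 10 splits of the control arrays.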

Results

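The series profiled transcripts of cells labelled MCF-10A with oncogenic cyclin E overexpression after knockdown of ATM, ATR, CHK1 or CHK2, the kinases that signal DNA damage and replication stress. Each of the 5 shRNAs was measured in 2 sets of 3 arrays, so each knockdown was compared with shControl on 12 arrays. A principal component analysis placed the 6 control arrays between -90.7 and -81.1 on the first component, which held 57.6% of the variance, and the 24 knockdown arrays between 9.20 and 30.9. The second component (19.6%) placed knockdown set 1 between 25 and 35.7 and knockdown set 2 between -31.8 and -21.8, with the controls between -8.60 and -6.90. Replicates correlated across genes at r = 0.988 to 0.996, and control arrays correlated with knockdown arrays of their set at r = 0.908 to 0.921. A pair of arrays stood apart from their replicates on the third component. Replicate 3 of shATR set 2 lay at 21.2 beside 1.60 and 3.60, and replicate 3 of shCHK2 set 1 lay at 30.1 beside 11.5 and 13.4.

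**Figure D1:**
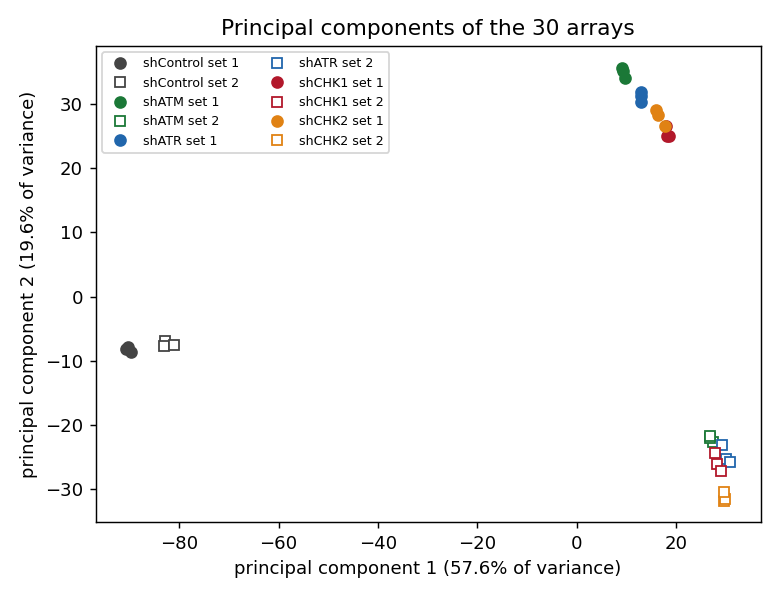
First and second principal components of the 30 arrays over all genes tested, one point per array, coloured by shRNA, with filled circles for set 1 and open squares for set 2. The control arrays lie at -81.1 or lower on the first component, and the second component separates the knockdown arrays of the sets.

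The targeted transcripts were read first, because they check the labels. ATM was lower in shATM than in shControl by a log2 difference of -0.49 (SE 0.07, n = 6 and 6, adjusted p = 2.8e-06), with -0.67 in set 1 and -0.30 in set 2. CHEK1, which encodes CHK1, was lower in shCHK1 by -0.78 (SE 0.08, adjusted p = 1.1e-09), with -0.38 in set 1 and -1.18 in set 2. CHEK2 was lower in shCHK2 by -0.35 (SE 0.09, adjusted p = 0.0015), with -0.55 in set 1 and -0.15 in set 2, where the adjusted p was 0.34. The CHEK2 call was lost with each group of 3 arrays as a random block, with means per shRNA and set, without a set term, and with median scaling (-0.24). The ATM call was lost with means. Against the mean of the other 3 knockdowns, the differences were -0.72 for ATM, -1.31 for CHEK1 and -0.55 for CHEK2 (SE 0.06, 0.06 and 0.07). ATR stood near background, with its main probe detected on 13 of 30 arrays, and was higher in the arrays labelled shATR by 0.34 (SE 0.11, adjusted p = 0.012). The label of those arrays could therefore not be checked from its transcript, and they are called the arrays labelled shATR. Statements about the 4 knockdowns count them by that label. Against the other knockdowns, a further detected ATM probe differed in shATM by -0.70 in set 1 and -0.56 in set 2, and a further CHEK2 probe in shCHK2 by -0.69 and -0.73. Against shControl these probes gave -0.71 and -0.92, and -1.40 and -0.46. Part of that was shared, as the ATM probe stood at -0.42 to -0.27 in the other knockdowns of set 2 and the CHEK2 probe at -0.82 to -0.56 in those of set 1.

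CCNE1, the gene for cyclin E1, was measured at a lower level in every knockdown than in shControl. Its log2 difference was -1.14 in shATM, -2.05 in the arrays labelled shATR, -1.78 in shCHK1 and -1.99 in shCHK2 (SE 0.09 each, n = 6 and 6). The labels do not say whether the probe reads the overexpressed transcript.

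**Figure D2:**
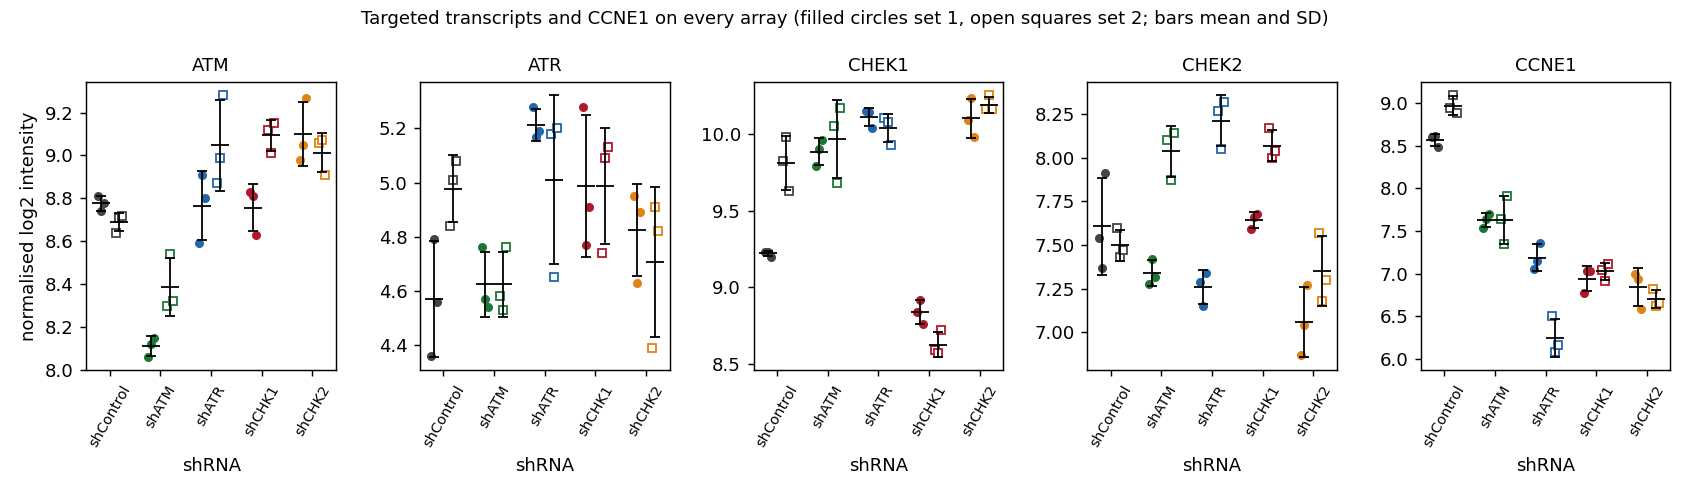
Normalised log2 intensity of ATM, ATR, CHEK1, CHEK2 and CCNE1 on each array by shRNA, with filled circles for set 1, open squares for set 2, and bars for the mean and SD of 3 arrays. ATM, CHEK1 and CHEK2 are lower in the arrays of their own shRNA than in the other knockdowns, by -0.72, -1.31 and -0.55, and CCNE1 is lower in all 4 knockdowns than in shControl.

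The comparisons with shControl that follow also hold a difference between control and knockdown cells, described further on. CDKN2A, for example, was detected on 0 of 6 control and 24 of 24 knockdown arrays. Those comparisons cannot be read as the effect of a knockdown alone. In shATM cells, inflammatory genes were higher than in shControl on average over the sets, and genes of luminal breast cells and of the NRF2 oxidative stress programme were lower. IL1B, a proinflammatory cytokine detected on all control arrays, rose by a log2 difference of 6.42 (SE 0.08, n = 6 and 6), and TFPI2, a protease inhibitor detected on 3 of 6, by 5.90 (SE 0.12). The compared probes of CCND2, a G1 cyclin, DKK3, a secreted Dickkopf protein, and FEZ1 were detected on no control array, and were at least 262-fold, at least 90.8-fold and at least 83.6-fold higher. MMP1, a collagenase detected on 1 of 6, was at least 232-fold higher. The gap junction gene GJA1 and the decoy receptor gene IL13RA2 were detected on no control array and were at least 61.7-fold and at least 41.1-fold higher. Among genes that fell, the retinoid-responsive RARRES1, the NADPH oxidase subunit CYBA and mesothelin (MSLN) were detected on all 6 control arrays and on none of shATM, and were at least 512-fold, at least 203-fold and at least 133-fold lower. COX7A1 and ANPEP were at least 56.7-fold and at least 59.5-fold lower. The matrix gene MGP (2 of 6 shATM arrays) and PLAAT3 (1 of 6) were at least 104-fold and at least 62.5-fold lower. CALB2 (4 of 6) fell by -7.11 (SE 0.13). Other probes of DKK3 ranged from -0.16 to 6.73, those of FEZ1, which were detected on control arrays, from 2.99 to 4.84, and those of RARRES1 from -8.83 to -5.34. The other CCND2 probe gave 6.79, and the other probes of CALB2 and PLAAT3 gave -0.71 and -0.31. The test called 4422 of 13721 genes in both sets, 1965 higher and 2457 lower.

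Of 25 measured inflammatory cytokines and NF-kB targets, 11 rose and 1 fell in shATM (11 and 1 adjusted over the list alone), among them IL24 (4.44, SE 0.11) and CSF3 (at least 20.2-fold, 1 of 6 control arrays), and the list was called (adjusted p = 1.1e-06). Its median was 2.30 in set 1 and 0.06 in set 2, where it was not called (adjusted p = 0.10). Among 19 NRF2 and oxidative stress genes, 11 fell and none rose (13 fell adjusted over the list alone, adjusted p = 1.1e-06), led by ALDH3A1 (-4.84, SE 0.12) and the aldo-keto reductases AKR1C2 (-4.71, SE 0.07) and AKR1C3 (-4.11, SE 0.07). Among 22 luminal genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 6.7e-05), led by the mucin MUC1 (-6.01, SE 0.11) and the keratin KRT23 (at least 8.34-fold lower). Of 17 basal genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0019), with KRT6C at 3.68 and KRT15 at -2.77. The basal call was lost at adjusted p = 0.065 with an estimated correlation. Of 38 oxidative phosphorylation genes, 10 fell and none rose (11 fell adjusted over the list alone, adjusted p = 0.012), such as NDUFA2 (-0.81, SE 0.07), and the call was lost at adjusted p = 0.16 with an estimated correlation. Of 28 keratinocyte differentiation genes, 9 fell and 4 rose (10 and 5 adjusted over the list alone, adjusted p = 0.027), with the kallikrein KLK7 at -4.41, and the call was lost at adjusted p = 0.10 with an estimated correlation. The median of that list was 0.38 in set 1 and -2.17 in set 2.

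The arrays labelled shATR differed from shControl in much the same genes. IL1B (6.72, SE 0.08) and TFPI2 (5.96, SE 0.12) rose, with n = 6 and 6. CCND2, MMP1, DKK3 and FEZ1 were at least 294-fold, at least 187-fold, at least 88.4-fold and at least 79.7-fold higher, while other FEZ1 probes gave 3.09 to 4.92 and other DKK3 probes 0.17 to 6.75. GJA1 and the microfibril gene FBN2 were at least 61.8-fold and at least 42.7-fold higher, with no control array detecting either. RARRES1, CYBA and COX7A1 were at least 530-fold, at least 210-fold and at least 58.7-fold lower, and MSLN was detected on none of the 6 arrays. PLAAT3 (0 of 6 by the compared probe) and MGP (2 of 6) were at least 65.4-fold and at least 119-fold lower. CALB2 (-7.27, 3 of 6) and MUC1 (-6.84, 5 of 6) fell with SE of 0.11 to 0.13. The other probes of PLAAT3 and CALB2 gave -0.19 and -0.84, those of MUC1 -6.48 to -2.62. The test called 4572 genes in both sets, 2074 higher and 2498 lower. The share higher was 45.4%, and 59.9% with median scaling. Replicate 3 of set 2, which stands apart on the third component (21.2), is among these arrays.

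Inflammatory genes rose in the arrays labelled shATR (12 of 25 rose and 1 fell, 12 and 1 adjusted over the list alone, adjusted p = 3.4e-07), with IL24 at 5.02 and CSF3 at least 28.5-fold higher. NRF2 genes fell (12 of 19, 12 adjusted over the list alone, adjusted p = 3.1e-06), as did luminal genes (12 of 22 fell and 1 rose, 12 and 1 adjusted over the list alone, adjusted p = 4e-05), with AKR1C2 at -5.03 and ERBB3 at -3.15. Keratinocyte differentiation genes fell (9 of 28 fell and 1 rose, 11 and 2 adjusted over the list alone, adjusted p = 0.0012), with CRABP2 at -4.90 and KLK5 at -4.10. The list's median was 0.07 in set 1, where camera pointed down at adjusted p = 0.98, and -2.51 in set 2. Genes of G2 and mitosis rose (11 of 32 rose and 2 fell, 11 and 2 adjusted over the list alone, adjusted p = 0.033), with the spindle genes TPX2 at 0.97 and AURKA at 0.82 and the centromere gene CENPF at -1.04. That call was lost within set 1 (adjusted p = 0.19), with the strict filter (0.061) and with chromosome medians subtracted (0.062). A further 4 lists were called and then lost. Basal genes (7 rose, 2 fell, adjusted over the list alone 7 and 2, adjusted p = 0.0068) stood at adjusted p = 0.083 with an estimated correlation. Epithelial junction genes (2 rose, 11 fell, adjusted over the list alone 2 and 11, adjusted p = 0.043), with CLDN1 at -2.55 and PKP1 at least 23-fold higher, stood at adjusted p = 0.087 with an estimated correlation. Oxidative phosphorylation genes (10 fell, 10 adjusted over the list alone, adjusted p = 0.0068) stood at adjusted p = 0.11 with an estimated correlation. Endothelial and fibroblast markers (3 of 6 fell, 4 adjusted over the list alone, adjusted p = 0.043), with PECAM1 at least 6.69-fold lower, stood at adjusted p = 0.083 with an estimated correlation.

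IL1B was also higher in shCHK1 than in shControl (6.66, SE 0.08, n = 6 and 6). CCND2, MMP1, DKK3 and FEZ1 were at least 308-fold, at least 207-fold, at least 99.4-fold and at least 74.1-fold higher, while other FEZ1 probes gave 2.86 to 4.71 and other DKK3 probes -0.22 to 6.78. GJA1, FBN2 and the cytoskeletal gene DPYSL3 were at least 54.5-fold, at least 50.4-fold and at least 44.8-fold higher. CYBA and PLAAT3 were at least 206-fold and at least 64.3-fold lower. RARRES1 and MSLN, each detected on 1 of 6 shCHK1 arrays, and the growth factor binding gene IGFBP3 (2 of 6) were at least 511-fold, at least 134-fold and at least 97.8-fold lower. CALB2 (-7.24, 3 of 6), MUC1 (-7.15, 6 of 6) and MGP (128-fold lower, 3 of 6) fell with SE of 0.11 to 0.13. The other probes of PLAAT3 and CALB2 gave -0.31 and -0.81, those of MUC1 -6.69 to -2.77. The test called 4589 genes in both sets, 2067 higher and 2522 lower, a share of 45% higher that was 52.1% with median scaling. Keratinocyte differentiation genes fell (16 of 28, none rose, 16 adjusted over the list alone, adjusted p = 8.5e-09), with the kallikreins KLK5 (-5.74, SE 0.09), KLK6 (-5.29, SE 0.13) and KLK7 (at least 44.4-fold lower). Luminal genes (12 of 22 fell and 1 rose, 12 and 1 adjusted over the list alone, adjusted p = 7.1e-06), NRF2 genes (10 of 19 fell, 11 adjusted over the list alone, adjusted p = 3.8e-06) and junction genes (12 of 23 fell and 1 rose, 12 and 1 adjusted over the list alone, adjusted p = 0.0088) fell, with ELF3 at -3.44, AKR1C3 at -4.53 and CLDN1 at -2.61. The junction list was not called by the list test within set 1 (adjusted p = 0.11). Inflammatory genes (11 of 25 rose and 2 fell, 11 and 2 adjusted over the list alone, adjusted p = 3.8e-06) and G2 and mitosis genes (14 of 32 rose and 2 fell, 14 and 2 adjusted over the list alone, adjusted p = 0.0088) rose, with IL24 at 5.12 and CDC20 at 0.85. Basal genes (8 rose, 2 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.044) were lost at adjusted p = 0.14 with an estimated correlation. Oxidative phosphorylation genes (11 fell, 10 adjusted over the list alone, adjusted p = 0.010) were lost at adjusted p = 0.13 with an estimated correlation.

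For shCHK2, IL1B (6.74, SE 0.08) and TFPI2 (5.53, SE 0.12) were higher than in shControl, with n = 6 and 6. CCND2, MMP1, DKK3 and FEZ1 were at least 257-fold, at least 145-fold, at least 95.7-fold and at least 73.9-fold higher, while other FEZ1 probes gave 3.05 to 4.87 and other DKK3 probes -0.19 to 6.80. GJA1 and DPYSL3 were at least 61-fold and at least 39.8-fold higher. RARRES1, CYBA and MSLN were at least 523-fold, at least 207-fold and at least 135-fold lower. CALB2 (-7.25, 5 of 6) and MUC1 (-7.06, 6 of 6) fell, as did MGP (-6.97), IGFBP3 (-6.70) and GDPD3 (-6.51), each detected on 3 of 6 shCHK2 arrays, with SE of 0.08 to 0.13. The other CALB2 probe gave -0.93, and other MUC1 probes gave -6.66 to -2.52. The test called 4649 genes in both sets, 2101 higher and 2548 lower. With median scaling, 59.6% rather than 45.2% were higher. Keratinocyte differentiation genes fell (15 of 28, 15 adjusted over the list alone, adjusted p = 4.6e-07), as did luminal genes (12 of 22, 12 adjusted over the list alone, adjusted p = 2e-05) and NRF2 genes (9 of 19 fell and 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 3.8e-05), with CRABP2 at -5.18, ELF3 at -3.51 and ALDH3A1 at -4.83. Inflammatory genes (12 of 25 rose and 2 fell, 12 and 2 adjusted over the list alone, adjusted p = 5.3e-07) and G2 and mitosis genes (14 of 32 rose and 1 fell, 14 and 1 adjusted over the list alone, adjusted p = 0.0016) rose, with CSF3 at least 27.8-fold higher, TPX2 at 1.05 and AURKA at 0.93. Junction genes (1 rose, 12 fell, 1 and 13 adjusted over the list alone, adjusted p = 0.019) were lost at adjusted p = 0.058 with an estimated correlation. Basal genes (6 rose, 2 fell, 6 and 2 adjusted over the list alone, adjusted p = 0.040) were lost at adjusted p = 0.15 with an estimated correlation, and were directed up in set 1 and down in set 2 (median -0.23). Oxidative phosphorylation genes (17 of 38 fell, 18 adjusted over the list alone, adjusted p = 0.0012) were lost at adjusted p = 0.075 with an estimated correlation. Replicate 3 of set 1, at 30.1 on the third component, is among these arrays and had the most detected probes of all, 21732.

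The series asks what defects of the replication stress response have in common, and most of the difference from shControl was shared. All 4 knockdowns called 3291 genes in the same direction, 1430 higher and 1861 lower, which is 54.8% of the 6007 genes called in any. IL1B rose (mean log2 difference 6.64, SE 0.06, 24 knockdown and 6 control arrays). Its difference was 8.33 to 8.41 over the knockdowns in set 1 and 4.52 to 5.08 in set 2, a spread that the SE leaves out. CCND2, MMP1, DKK3, FEZ1 and GJA1 were at least 280-fold, at least 190-fold, at least 93.4-fold, at least 77.7-fold and at least 59.7-fold higher, while other FEZ1 probes gave 3 to 4.83 and other DKK3 probes -0.10 to 6.77. CALB2 fell (-7.22, SE 0.10, 15 of 24, other probe -0.82), and RARRES1 and MSLN, each detected on 1 of 24 knockdown arrays, and MGP (10 of 24) were at least 519-fold, at least 135-fold and at least 111-fold lower. CYBA and COX7A1 were at least 207-fold and at least 57.7-fold lower. Independent lists would share 6.90 higher and 15.3 lower genes, the simulated unchanged groups shared 0, and the fit with controls split between knockdowns called 2531, of which 2521 were among the 3291. Neither the simulated groups nor the split controls can tell a shared knockdown effect from a difference between control and knockdown cells. The simulated groups lack such a difference, and every control array lies on the same side of it. Across genes, which are not independent replicates, the responses of any pair of knockdowns correlated at r = 0.963 to 0.985, against 0.497 to 0.5 in simulated unchanged groups with shared controls and 0.948 to 0.969 with split controls. Other kept probes existed for 1099 of the 3291 genes, and for 981 of these every other probe went the same way.

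Over the 4 knockdowns together, inflammatory genes rose (10 of 25 rose and 1 fell in all 4, 12 and 2 adjusted over the list alone, adjusted p = 4.5e-06), with a median of 1.95 in set 1 and 0.18 in set 2. NRF2 genes fell (8 of 19, 11 adjusted over the list alone, adjusted p = 8.7e-06), as did luminal genes (12 of 22, with 12 fallen and 1 risen adjusted over the list alone, adjusted p = 5e-05) and keratinocyte differentiation genes (8 of 28, 12 adjusted over the list alone, adjusted p = 5.5e-05). The keratinocyte median was -0.22 in set 1 (adjusted p = 0.071) and -2.46 in set 2. G2 and mitosis genes rose (8 of 32 rose and 1 fell, 14 and 4 adjusted over the list alone, adjusted p = 0.038), with adjusted p = 0.13 in set 1. Oxidative phosphorylation genes (6 of 38 fell, 16 adjusted over the list alone, adjusted p = 0.0026) were lost at adjusted p = 0.10 with an estimated correlation. Junction genes (9 of 23 fell and 1 rose, 12 and 2 adjusted over the list alone, adjusted p = 0.038) were lost at adjusted p = 0.088 with an estimated correlation. Basal genes (5 of 17 rose and 2 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.018) were lost at adjusted p = 0.10 with an estimated correlation.

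Of the lists called, 3 held with an estimated correlation for shATM, 5 for the arrays labelled shATR, 6 for shCHK1, 5 for shCHK2 and 5 over the 4 together. Lists called in the same direction in each set numbered 2 of 6, 4 of 9, 5 of 8, 6 of 8 and 4 of 8.

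The other 18 lists were not called over the 4 knockdowns together. Checkpoint signalling genes went both ways (4 of 24 rose and 1 fell in all 4, 5 and 4 adjusted over the list alone), with H2AX at 1.28 and TIMELESS at -0.84. Of 39 DNA replication genes 2 fell (3 rose and 9 fell adjusted over the list alone), of 22 genes of homologous recombination and fork protection 3 rose and 2 fell (5 and 3 adjusted over the list alone), and of 16 E2F regulators 3 rose and 3 fell (3 and 3 adjusted over the list alone). The E2F median was 0.15 while its mean was -0.07. Of 21 histones 4 fell (10 adjusted over the list alone), and of 26 p53 targets 3 rose and 5 fell (4 and 8 adjusted over the list alone), with MDM2 at 2.42 and GDF15 at -3.40. Of 31 interferon genes 2 rose and 3 fell (8 and 6 adjusted over the list alone), with IFITM3 at 4.92. Of 16 MHC class I genes 2 rose and 1 fell (2 and 2 adjusted over the list alone). Of 24 mesenchymal and matrix genes 4 rose and 4 fell (5 and 5 adjusted over the list alone), with SNAI2 at 5.35, VIM at 2.78 and S100A4 at -5.43. The median was -0.05 while the mean was 0.19. Of 22 TGF-beta and YAP targets 6 rose and 2 fell (9 and 2 adjusted over the list alone), with AXL at 3.35. Of 19 breast stem and progenitor genes 4 rose and 1 fell (5 and 5 adjusted over the list alone). Of 23 ERK pathway genes 4 rose and 1 fell (6 and 2 adjusted over the list alone), with FOSL1 at 1.89. Of 25 hypoxia and glycolysis genes 3 rose and 2 fell (4 and 5 adjusted over the list alone). Of 24 integrated stress and unfolded protein response genes 1 rose and 4 fell (4 and 4 adjusted over the list alone), of 20 cholesterol synthesis genes 5 fell (2 rose and 6 fell adjusted over the list alone), and of 39 ribosomal protein genes 1 rose and 5 fell (1 and 9 adjusted over the list alone). Markers of other cell types did not rise, since 3 of 6 endothelial and fibroblast markers (4 adjusted over the list alone) and 2 of 11 leukocyte markers (2 adjusted over the list alone) fell, the latter with a median of 0.01 and a mean of -0.51.

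**Figure D3:**
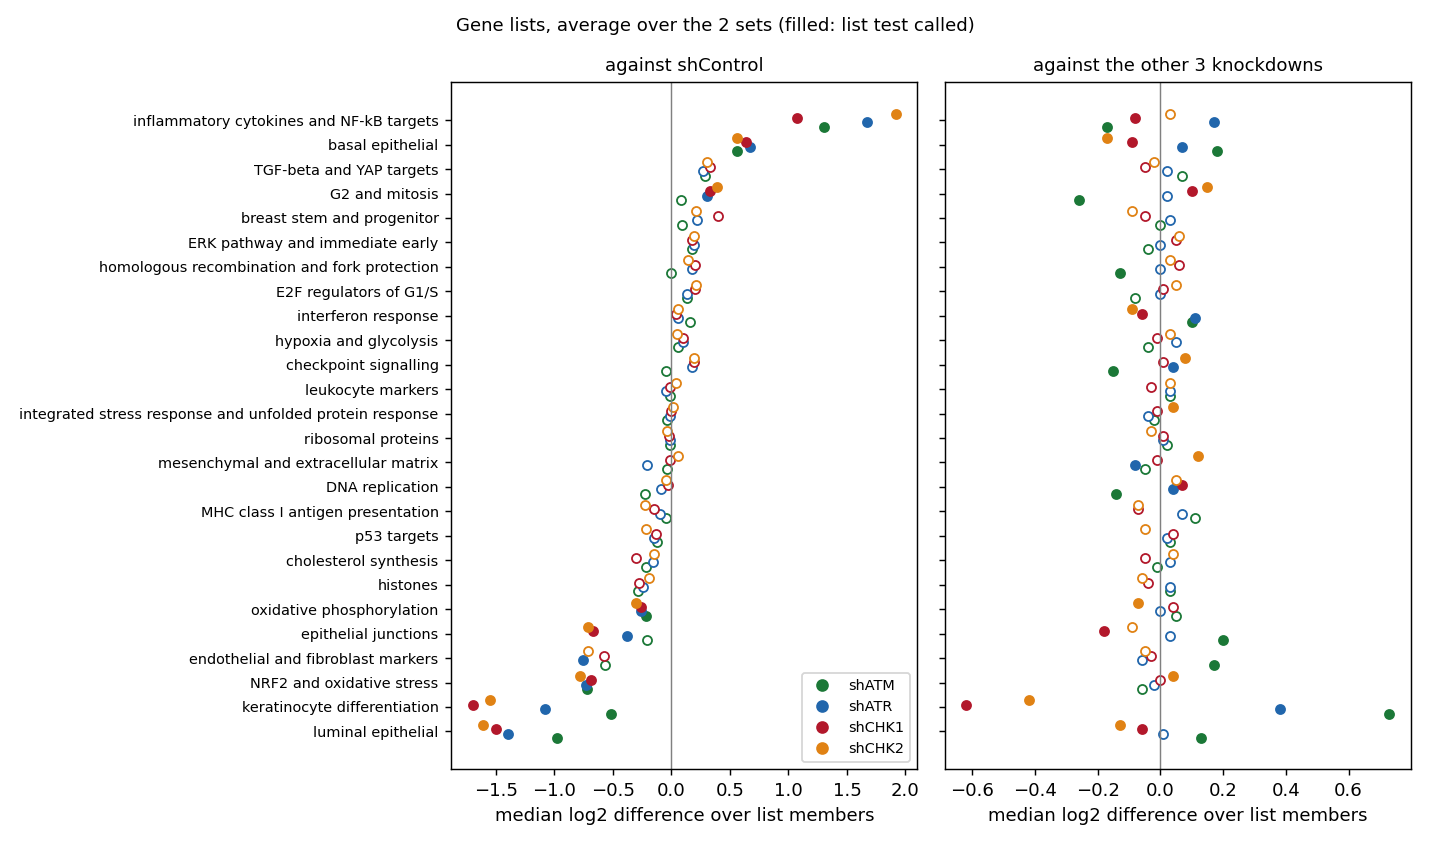
Median log2 difference over the measured members of each of the 26 gene lists, averaged over sets, for each knockdown against shControl (left) and against the other 3 knockdowns (right), with filled points where the list test was called. Inflammatory genes lie to the right and luminal, keratinocyte and NRF2 genes to the left of 0 in every knockdown against shControl.

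The targets form 2 kinase pairs, ATR with CHK1 and ATM with CHK2, and few genes separated the pairs. The glucose transporter SLC2A3 (-0.91, SE 0.05, n = 12 and 12), the kallikrein KLK5 (-0.96, SE 0.06), the proteoglycan VCAN (-1.21, SE 0.09), the receptor GPR37 (-0.82, SE 0.08), NUDT11 (-0.68, SE 0.05) and the sialyltransferase ST6GAL1 (-0.83, SE 0.08) were lower in the mean of the arrays labelled shATR and shCHK1 than in that of shATM and shCHK2. All 6 were lowest in shCHK1. Against the other 3 knockdowns the arrays labelled shATR stood at -0.09 for SLC2A3 and -0.08 for GPR37, and were higher for KLK5 (0.45) and VCAN (0.36), with KLK5 above shCHK2 (0.06). SDHA, a subunit of succinate dehydrogenase (0.32, SE 0.05), DMBT1 (0.42, SE 0.07) and PRELID3A (0.35, SE 0.06) were higher. The test called 26 genes in both sets, 3 higher and 23 lower (11.5% higher), and 8 with median scaling, none of them higher. With values averaged over probes the DMBT1 difference was 0.18 and not called. Keratinocyte differentiation genes were lower (3 of 28 fell, 6 adjusted over the list alone, adjusted p = 3e-15), with S100A8 and S100A9 at -0.32 each. The list test also placed junction genes (none called, 3 fell adjusted over the list alone, adjusted p = 4.8e-06), luminal genes (none called, 1 fell adjusted over the list alone, adjusted p = 0.00067) and matrix genes (none called, adjusted p = 0.0016) lower, and DNA replication genes (adjusted p = 3.3e-06) and G2 and mitosis genes (adjusted p = 4.8e-06), with none called, higher. Checkpoint genes (1 of 24 fell, CHEK1 at -0.63, and 2 rose and 1 fell adjusted over the list alone, adjusted p = 0.010, directed up) were lost at adjusted p = 0.066 with an estimated correlation. Of the 7 lists, 2 were called in each set. In set 2 the adjusted p was 0.95 for DNA replication, 0.21 for G2 and mitosis, 0.21 for luminal, 0.59 for checkpoint and 0.81 for matrix genes.

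Because the difference from shControl was so widely shared, each knockdown was also compared with the other 3, a comparison added after the data had been seen. In shATM, epidermal differentiation and basal keratin genes were higher and cell division genes lower than in the other knockdowns. The DNA repair gene MGMT (1.89, SE 0.08, n = 6 and 18), the histone variant gene MACROH2A2 (1.83, SE 0.09), GBP6 (1.79, SE 0.12), NCCRP1 (1.55, SE 0.12), TMEM98 (1.53, SE 0.11), SCGB1A1 (2.83-fold, SE 0.11), S100P (1.42, SE 0.07) and IL1RN (1.34, SE 0.11) were higher. SGPP2 (at least 2.08-fold, 2 of 6 shATM arrays), AP1AR (-0.83, SE 0.07), TUSC1 (-0.77, SE 0.14), ATM itself (-0.72, SE 0.06), FAM241A (-0.70), ABCC3 (-0.69), NRP1 (-0.69) and HELQ (-0.67) were lower, and the other NRP1 probe gave 0. The test called 355 genes in both sets, 243 higher and 112 lower. Of the genes called, 68.5% were higher, and 23.8% with median scaling. The other probes of TMEM98 and IL1RN gave 0.35 and 0.25. Keratinocyte differentiation genes rose (8 of 28, 11 risen and 1 fallen adjusted over the list alone, adjusted p = 3.5e-25), with KLK5 at 1.22 and S100A7 at 1.07, as did basal (6 of 17, 8 and 1 adjusted over the list alone, adjusted p = 1.2e-05), luminal (6 of 22, 8 and 1 adjusted over the list alone, adjusted p = 5.4e-06) and junction genes (3 of 23, 4 adjusted over the list alone, adjusted p = 8.2e-07). G2 and mitosis genes fell (3 of 32, 6 adjusted over the list alone, adjusted p = 8.2e-18), with cyclin A2 (CCNA2) at -0.59 and CENPE at -0.43, as did DNA replication genes (1 of 39, none adjusted over the list alone, adjusted p = 3e-07), which were not called in set 2 (adjusted p = 0.61). Inflammatory genes (2 rose, 2 fell, 2 and 2 adjusted over the list alone, adjusted p = 0.045, median -0.17) were lost at adjusted p = 0.11 with an estimated correlation, and were directed up in set 1 and down in set 2. Checkpoint genes were placed lower (adjusted p = 0.00033, 0.50 in set 2) and interferon genes higher (adjusted p = 0.021; 1 of 31 rose, SAMD9 at 0.62). Interferon genes pointed down in set 2 while their median was 0.03. Homologous recombination genes (adjusted p = 0.028) were placed lower and endothelial and fibroblast markers (adjusted p = 0.028) higher, with no member called. Of the 11 lists, 5 were called in the same direction in each set.

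The arrays labelled shATR differed least from the other knockdowns, with 3 genes higher and 2 lower in both sets (60% higher), and with median scaling 3 genes, all of them higher. CHEK1 (0.47, SE 0.06, n = 6 and 18), the bicarbonate transporter SLC4A7 (0.39, SE 0.06) and the chemokine CCL20 (0.37, SE 0.06) were higher, and KYNU, an enzyme of tryptophan breakdown (-0.99, SE 0.05), and TXNIP (-0.45, SE 0.08) were lower. CHEK1 was low in one comparator, shCHK1. Keratinocyte differentiation genes were placed higher by the list test, with no member called (adjusted p = 1.4e-30), at a median of 0.73 in set 1 and -0.09 in set 2. Inflammatory genes were placed higher (1 of 25 rose, 2 adjusted over the list alone, adjusted p = 1.1e-09), at -0.03 in set 1, where the test pointed up, and 0.23 in set 2. Checkpoint genes (1 rose, CHEK1, adjusted p = 0.0049) and interferon genes (none called, adjusted p = 0.005) were placed higher and matrix genes (none called, adjusted p = 0.00057) lower. Basal genes (none called, adjusted p = 0.005) were lost at adjusted p = 0.082 with an estimated correlation. DNA replication genes (none called, adjusted p = 0.033) were lost at adjusted p = 0.14 with an estimated correlation. None of the 7 lists was called in the same direction in each set. The count of 5 was 3 without shATR set 1 replicate 2 or set 2 replicate 3, and 8 without shCHK2 set 1 replicate 3.

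In shCHK1, the matrix proteoglycan VCAN (-1.97, SE 0.10, n = 6 and 18), KLK5 (-1.73, SE 0.07), CHEK1 (-1.31, SE 0.06), SLC2A3 (-1.13, SE 0.06), GPR37 (at least 1.79-fold, 1 of 6 shCHK1 arrays), the neuropeptide gene NMU (-0.99, SE 0.09) and the carbonic anhydrase gene CA2 (-0.98, SE 0.05) were lower, and the cadherin CDH11 was at least 2.21-fold lower. The adhesion gene NRCAM (0.79, SE 0.07), SCARNA9 (0.59, SE 0.09), MACROH2A2 (0.49), MOCS2 (0.46), ANKRD50 (0.39), TRIM4 (0.36), DNAL4 (0.35) and XKR6 (0.34) were higher, and averaged over probes MOCS2 (0.15) and XKR6 (0.04) were not called. The other TRIM4 probe gave 0.08. These SE leave out the spread between sets. In set 1 and set 2, VCAN stood at -2.9 and -1.03, KLK5 at -2.49 and -0.98, and CA2 at -1.65 and -0.31. CHEK1 was closer, at -1.19 and -1.43. MACROH2A2 stood at 0.14, not called, in the authors' values and without background correction. It was low in shCHK2, a comparator (-2.13 against the others), and high in shATM (1.83). The test called 48 genes, 11 higher and 37 lower (22.9% higher), and 31 without replicate 3 of set 2. With median scaling it called 23, of which 8.7% were higher. Keratinocyte differentiation genes were lower (2 of 28 fell, 5 adjusted over the list alone, adjusted p = 1.3e-45), at -1.14 in set 1 and -0.08 in set 2. Junction genes (none called, adjusted p = 2e-07) were lower and G2 and mitosis genes (none called, adjusted p = 0.00016) higher, the latter at 0.20 in set 1 and -0.02 in set 2. Basal genes (1 fell, KRT16 at -0.66, adjusted p = 7.9e-05), luminal genes (none called, adjusted p = 0.00028) and inflammatory genes (none called, adjusted p = 0.00079) were placed lower and DNA replication genes (none called, adjusted p = 0.0034) higher. Interferon genes (none called, adjusted p = 0.018) were lost at adjusted p = 0.05 with an estimated correlation. None of the 8 lists was called in the same direction in each set.

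In shCHK2, the surface glycoprotein gene THY1 (1.98, SE 0.05, n = 6 and 18), REPIN1 (1.48, SE 0.09), KYNU (1.42, SE 0.05), VCAN (1.17, SE 0.10), TUSC1 (1.06, SE 0.14), GSPT2 (0.94, SE 0.09), CDH11 (0.93, SE 0.08) and NAP1L5 (at least 1.57-fold, 6 of 18 comparator arrays) were higher. MACROH2A2 (-2.13, SE 0.09), MGMT (-1.62, SE 0.08), SCGB1A1 (-1.46), GBP6 (-1.17), the Notch target HES4 (-1.13), IRX5 (-1.03), NCCRP1 (-1.03) and PHACTR3 (-1) were lower. VCAN and CDH11 were low in shCHK1, a comparator, where CDH11 was detected on no array. From the mean of the 4 knockdowns, VCAN stood at 0.87 in shCHK2, 0.33 in shATM, 0.27 in the arrays labelled shATR and -1.47 in shCHK1. MACROH2A2, MGMT, SCGB1A1, GBP6 and NCCRP1 were high in shATM, also a comparator. The other probes of REPIN1, GBP6 and NCCRP1 gave 0.05, -0.39 and -0.36. The test called 214 genes, 85 higher and 129 lower, and 136 without replicate 3 of set 2. The share of called genes that were higher was 39.7%, and with median scaling 63.4% of 112. G2 and mitosis genes were higher (1 of 32 rose, CCNA2 at 0.45, 1 adjusted over the list alone, adjusted p = 1.7e-09), and keratinocyte differentiation genes lower (1 rose and 1 fell, 1 and 1 adjusted over the list alone, adjusted p = 3.5e-12), with LCN2 at -0.65 and KRT80 at 0.70. NRF2 genes were higher (2 of 19 rose, 2 adjusted over the list alone, adjusted p = 0.014), with TXNRD1 at 0.43 and NQO1 at 0.42, and basal genes lower (3 of 17 fell, 4 adjusted over the list alone, adjusted p = 6.9e-05), with KRT14 at -0.68. A further 6 lists were called and lost. Checkpoint genes (1 rose, 1 fell, adjusted p = 0.043) stood at adjusted p = 0.13 with an estimated correlation. Stress response genes (3 rose, adjusted p = 0.0083) stood at adjusted p = 0.22 with an estimated correlation. Interferon genes (2 fell, adjusted p = 0.010) stood at adjusted p = 0.055 with an estimated correlation. Luminal genes (1 fell, SLPI at -0.71, adjusted p = 0.0058) stood at adjusted p = 0.095 with an estimated correlation. Matrix genes (1 rose, 1 fell, adjusted p = 0.0075) stood at adjusted p = 0.08 with an estimated correlation. Oxidative phosphorylation genes (none called, adjusted p = 0.0058) stood at adjusted p = 0.12 with an estimated correlation. None of the 10 lists was called in the same direction in each set. The adjusted p was 0.09 for G2 and mitosis, 0.13 for keratinocyte and 0.29 for NRF2 genes in set 2, and 0.19 for basal genes in set 1.

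The control cells of the sets differed as well. In shControl set 2, inflammatory, interferon, antigen presentation and p53 target genes were higher than in set 1, and NRF2 genes were lower. Of 25 inflammatory genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 1.8e-08), with CXCL1 at 2.27 (SE 0.14, n = 3 and 3) and IL1B at 2.08 (SE 0.11). Of 26 p53 targets 14 rose (14 adjusted over the list alone, adjusted p = 3.1e-08), with GADD45A at 1.22 and PMAIP1 at 1.11. Of 31 interferon genes 12 rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 1.1e-05), with ISG15 at 1.35. Of 16 MHC class I genes 8 rose (10 adjusted over the list alone, adjusted p = 6.3e-06), with HLA-B at 1.41. DNA replication genes rose (11 of 39, 18 adjusted over the list alone, adjusted p = 2.8e-06). NRF2 genes fell (15 of 19, 15 adjusted over the list alone, adjusted p = 6.6e-19), with GPX2 at -4.12 (SE 0.27) and AKR1B10 at -2.73 (SE 0.15). Homologous recombination genes rose (5 of 22, adjusted p = 0.011) and histones fell (4 of 21, adjusted p = 0.020). Another 7 lists were called and lost with an estimated correlation, at adjusted p = 0.16 for basal, 0.058 for E2F, 0.076 for endothelial and fibroblast, 0.17 for hypoxia, 0.34 for stress response, 0.16 for luminal and 0.16 for matrix genes. The test called 2106 genes, 1121 higher and 985 lower. The share higher, 53.2%, was 68.8% with median scaling.

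Chromosome by chromosome, the genes of 5 chromosomes were shifted as a body by more than 0.1 between the knockdowns and shControl. The median log2 difference was -0.36 on chromosome 16 (609 genes), -0.22 on chromosome 7 (660 genes), -0.19 on chromosome 4 (492 genes), -0.11 on chromosome 8 (507 genes) and 0.32 on chromosome 20 (371 genes), with the same sign in each set. CYBA, MSLN, CALB2 and GDPD3 lie on chromosome 16. The SD of the chromosome medians was 0.131, and the highest of 1000 shuffles of genes over chromosomes gave 0.040 (permutation p = 0.001, the smallest they can give). Between the shControl sets the SD was 0.0191, and the shuffles gave up to 0.0248 (permutation p = 0.014).

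**Figure D4:**
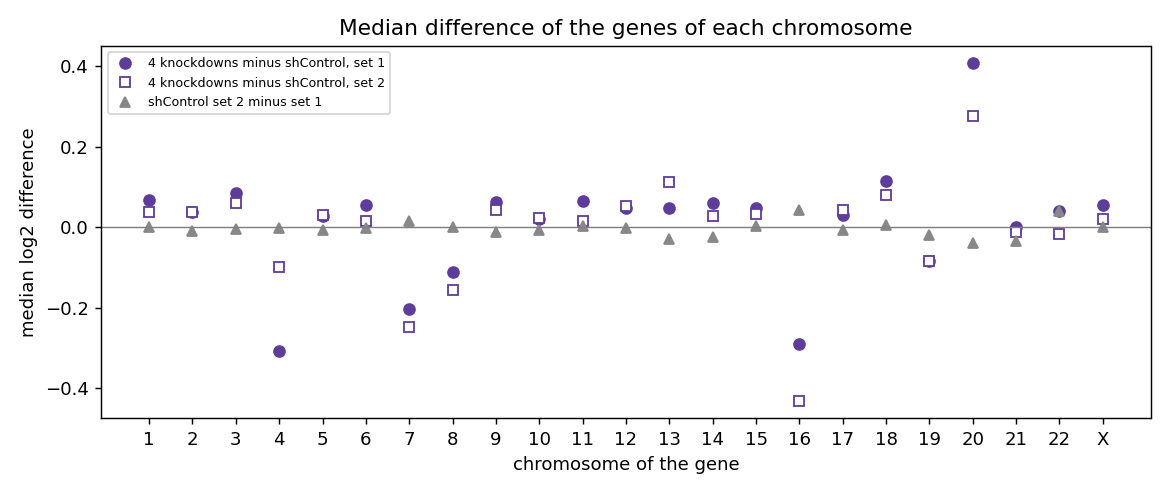
Median log2 difference of the genes of each chromosome, for the mean of the 4 knockdowns minus shControl in set 1 (filled circles) and set 2 (open squares) and for shControl set 2 minus set 1 (triangles). Chromosome 20 lies at 0.41 and 0.28 and chromosome 16 at -0.29 and -0.43 in the sets, while the triangles lie between -0.04 and 0.04.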

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

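The tests of genetic background, a single line, single loci, the size of change after subtracting chromosome medians, normalization of the common difference, the common kinase effect, shared array processing, small RNA yield and chromosome dosage among the knockdowns were chosen only after the results were seen.

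The response to each knockdown differed between the sets by the interaction test in 4092 genes for shATM, 3924 for the arrays labelled shATR, 4066 for shCHK1 and 4449 for shCHK2. Of the 16 most changed genes named per knockdown, 12, 11, 10 and 10 differed between the sets. The difference from the other knockdowns changed between sets in 1015, 608, 793 and 920 genes, and the contrast of the kinase pairs in 978. Among the targets, set 2 minus set 1 was -0.61 for ATR in the arrays labelled shATR (adjusted p = 0.044, near background), -0.80 for CHEK1 in shCHK1 (adjusted p = 0.00019), and for CCNE1 -1.35 in the arrays labelled shATR (adjusted p = 3.9e-06) and -0.55 in shCHK2 (adjusted p = 0.026). Of the probes without a gene name, which the comparisons did not use, 662 were changed in all 4 knockdowns.

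The common difference of all 4 knockdowns from shControl came with the shift of whole chromosomes (SD of chromosome medians 0.1312), as cells of different genetic background would show. CDKN2A and MTAP, which MCF-10A cells are known to lack, were detected on all 24 knockdown arrays, which argues against a single line lacking them on all arrays. Of 16 testable genes at loci prone to deletion, chosen after the values were seen, 37.5% were detected on all arrays of one side and at most 2 of the other. That held for 2.49% of all genes, and the 37.5% lay between the outcomes set for that test. With chromosome medians subtracted, 87.2% of the genes called in all 4 stayed called, between the bounds written beforehand, and their median absolute difference kept 95.3% of its size. The chromosome medians lay between -0.36 and 0.32, so subtracting them could remove little of a median absolute difference of 1.03. That argues against a shift of whole chromosomes as the whole cause, while dosage of parts of chromosomes was not tested. The count was 3349 in the less favourable of the authors' values and no background correction, which argues against background correction as the cause. Both are quantile normalized like the main values, so they cannot decide on quantile normalization. A common effect of losing the kinases (54.8% of called genes shared) cannot be told apart from any other difference between the control and knockdown cultures, because every control array lies on one side of the background difference. The mean log2 levels of CDKN2A (4.58 on control and 8.84 on knockdown arrays) and MTAP (4.78 and 10.1) argue against the same cells on both sides. Which cells the knockdown arrays hold, and whether labels or cultures account for it, stays open. Comparisons with shControl hold that difference too, and cannot be read as the effect of a knockdown alone.

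The difference between knockdown sets (8031 genes) went largely its own way, as the controls' set difference correlated with that of each knockdown at r = 0.04 or below across genes, which argues against array processing shared by a set as the whole cause. Of 1493 genes called in controls and knockdowns 791 went the same way, GPX2 and AGR2 among them, and 702 the opposite way. The count was 8028 in the less favourable of the authors' values and no background correction, which argues against background correction for the count. Both are quantile normalized, so they cannot decide on quantile normalization, and the share higher went from 42.8% to 31.1% with median scaling. Small RNA yield as the whole cause is argued against by the 59.5% of protein coding genes tested that were called, although snoRNAs had a median of 0.36 against -0.04 for protein coding genes. Chromosomes were shifted between the knockdown sets as well. The SD of the chromosome medians was 0.037, and the highest of 1000 shuffles gave 0.0294 (permutation p = 0.001). The largest medians were -0.126 on chromosome 20, 0.086 on chromosome 4 and -0.079 on chromosome 16. Populations that differ in chromosome dosage may therefore contribute. No other biological explanation was tested, because the labels do not say what the sets are.

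Differences among the knockdowns also came with chromosome shifts. The lowest ratio of the SD of chromosome medians to its shuffled mean was 1.75 over the 4 knockdowns, so populations that differ in chromosome dosage may contribute. That ratio was of the arrays labelled shATR on average over the sets. Within single sets the ratios were 2.39 to 3.76. Some shifts changed sign, as chromosome 5 in the arrays labelled shATR stood at 0.122 in set 1 and -0.085 in set 2. Of the 112 genes lower in shATM 24 lie on chromosome 4 (Fisher's exact test, adjusted p = 8.8e-12), and of the 85 higher in shCHK2 41 do (adjusted p = 1.2e-35). That chromosome holds 3.6% of the genes tested. On chromosome 5, with 4.4%, lie 12 of the 112 (adjusted p = 0.019). Only these chromosomes were tested, and their medians stood out in the same comparisons. The tests also take genes as independent, so they restate the shifts and add no separate support. The keratinocyte differentiation list stayed called in 4 of 4 knockdowns with chromosome medians subtracted. Against the other knockdowns those medians lay between -0.072 and 0.067 on average over the sets, so subtracting them could change the calls little. That outcome was nearly fixed beforehand and cannot decide on chromosome dosage for the list. Dosage of smaller regions was not tested. The effect of each kinase stays open.

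For the counts in both sets, 1 of 100 random splits of the same arrays, the real one, gave as many genes, and the highest other split gave 0. That held for shATM (4422), the arrays labelled shATR (4572), shCHK1 (4589), shCHK2 (4649), all 4 (3291), the kinase pairs (26) and each knockdown against the others (355, 5, 48 and 214). Splits against shControl mix arrays that lie far apart, which widens the spread within groups, so a count of 0 was nearly fixed beforehand. The splits also take arrays as units, so they cannot exclude differences between cultures. For the averages, 1 of 100 gave as many (8039, 8192, 8184 and 8390), with 5535, 5714, 5523 and 5908 the highest others, and for the knockdown sets 1 of 100 (8031, highest other 2596). For the differences between sets 8 of 100 splits gave as many genes, and up to 5555, 5608, 5479 and 5776. Arrays were swapped within each set, so a split can turn the difference between knockdown and shControl into a difference between sets. These splits therefore cannot decide on chance for those counts. For the number of lists called, 52, 10, 15 and 20 of 100 splits gave as many against shControl (6, 9, 8 and 8 lists, highest others 13, 11, 11 and 12), 9, 29, 16 and 7 against the other knockdowns (11, 7, 8 and 10 lists, highest others 13, 13, 13 and 12) and 20 for the kinase pairs (7 lists, highest other 14), so chance is not excluded for those numbers. Splits against shControl can keep part of the difference between knockdown and shControl, so for those lists they cannot decide the question. The 10 splits of the control arrays are too few for a share under 0.05 (2106 genes, highest other 1).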

How the results depend on the processing

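The fit without the 2 arrays that stand apart, the subtraction of chromosome medians, and the comparisons of knockdowns with each other and of knockdown sets were chosen after seeing the data. The chip could not be used as a block because the files give none, and the minimum of 1.5-fold was not applied to lists. No target and no other named gene changed direction. With median scaling, genes called higher went from the minority of called genes to the majority, or the reverse, in several comparisons. Where a value differs below, the cause was not tested unless stated.

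A minimum of 1.5-fold asks for more, and left 2585, 2738, 2741 and 2783 genes in both sets for shATM, the arrays labelled shATR, shCHK1 and shCHK2, 3997, 4094, 4102 and 4253 on average, 1929 for all 4, 6 for the kinase pairs, 1020 between shControl sets, 2216 between knockdown sets, and 68, 0, 11 and 40 against the other knockdowns (limma; for the arrays labelled shATR 1287 genes had an unadjusted p under 0.05). ATM (-0.49), ATR (0.34) and CHEK2 (-0.35 against shControl, -0.55 against the other knockdowns) then missed the threshold. With each group of 3 as a random block (correlation of arrays within a group 0.571) the averages called 3600, 3768, 3814 and 3948 genes, and with means per shRNA and set 2117, 2375, 2397 and 2473. ATR (0.34) and CHEK2 (-0.35) were not called in either, nor ATM (-0.49) with means. CHEK2 was also not called without a set term (-0.35) or with median scaling (-0.24), nor ATR averaged over probes (0.21).

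Median scaling moved the median of all genes by -0.11 to 0.10 over the comparisons, and gave 3, 23 and 112 genes for the arrays labelled shATR, shCHK1 and shCHK2 against the others, 8 for the kinase pairs, and 13 lists for the pairs and 11 for the arrays labelled shATR against the others. The share of called genes that were higher went from 45.4% to 59.9% for the arrays labelled shATR, from 45% to 52.1% for shCHK1, from 45.2% to 59.6% for shCHK2, and against the others from 68.5% to 23.8% for shATM and from 39.7% to 63.4% for shCHK2. On average over sets it went from 49.5% to 61.2%, 49.6% to 55.5% and 49.6% to 61% for the arrays labelled shATR, shCHK1 and shCHK2. Lists for the pairs numbered 11 without the filter and 12 within set 1. The 5 genes of the arrays labelled shATR were 9 in the authors' values, 9 without background correction and 3 with a replicate block. The estimated correlation left 3, 5 and 5 lists for shATM, the arrays labelled shATR and shCHK2, and 4 for shCHK2 against the others. Against the others, shCHK1 called 13 lists within set 1 and 2 within set 2, and shCHK2 called 1 within set 2.

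Single lists turned within a set. In set 1 these were keratinocyte differentiation for shATM (adjusted p = 0.52) and inflammatory genes for shATM against the others (0.037). In set 2 they were basal genes for shCHK2 (0.70), matrix genes for the pairs (0.81), and against the others homologous recombination (0.70) and interferon (0.99) for shATM, interferon (0.54) and keratinocyte differentiation (0.16) for the arrays labelled shATR, and DNA replication (0.17), G2 and mitosis (0.63), inflammatory (0.38) and interferon genes (0.025) for shCHK1.

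Leaving out each array in turn gave 3 to 8 genes for the arrays labelled shATR against the others, 31 to 47 for shCHK1 and 136 to 261 for shCHK2, and 0.27 to 0.41 for ATR, which was called without replicate 2 of set 2. All 4 knockdowns shared 3127 to 3348 genes. Arrays of equal number did not pair (deviations correlated at -0.06 to 0.10). Signal over background of 16 to 23.5 limits what can be said of genes near background, such as ATR.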

Other observations

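All comparisons in this part, and the genes at single loci, were chosen after the data had been seen.

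The knockdown cells of set 2 had less of the epidermal, inflammatory and antioxidant transcripts than those of set 1, in all 4 knockdowns averaged. Of 28 keratinocyte differentiation genes 27 fell and 1 rose (27 and 1 adjusted over the list alone, adjusted p = 9.5e-16), with the cornified envelope genes SPRR1B at -3.86 (SE 0.09, n = 12 and 12) and SPRR3 at least 7.82-fold lower (0 of 12 set 2 arrays). Of 25 inflammatory genes 22 fell and 1 rose (23 and 1 adjusted over the list alone, adjusted p = 8.1e-11), with the metalloproteinases MMP10 at -6.08 (SE 0.09) and MMP3 at least 11-fold lower (1 of 12). Basal genes (16 of 17 fell, 16 adjusted over the list alone, adjusted p = 8.7e-09), junction genes (20 of 23 fell, 20 adjusted over the list alone, adjusted p = 4.9e-08), ERK pathway genes (21 of 23 fell, 21 adjusted over the list alone, adjusted p = 1.5e-07) and NRF2 genes (17 of 19 fell and 2 rose, 17 and 2 adjusted over the list alone, adjusted p = 4.9e-08) fell, with KRT15 at -3.72, JUP at -1.80, HBEGF at -2.52 and AKR1C2 at -3.75. Interferon genes fell (22 of 31 fell and 2 rose, 22 and 2 adjusted over the list alone, adjusted p = 4e-05), with IFIT1 at -1.66. DNA replication genes rose (21 of 39 rose and 6 fell, 21 and 6 adjusted over the list alone, adjusted p = 0.00068), with POLE2 at 0.80 and MCM10 at 0.73, as did genes of homologous recombination (11 of 22 rose and 1 fell, 11 and 1 adjusted over the list alone, adjusted p = 0.0053), with BRCA1 at 0.76. Luminal genes fell (16 of 22 fell and 1 rose, adjusted p = 3.1e-05) and G2 and mitosis genes rose (14 of 32 rose and 7 fell, adjusted p = 0.022). Hypoxia, stress response and MHC class I genes were called lower and lost, at adjusted p = 0.31, 0.31 and 0.091 with an estimated correlation. In shControl, inflammatory and interferon genes had been higher in set 2, while NRF2 genes fell (15 of 19) and DNA replication and homologous recombination genes rose there too.

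Several genes were detected on all arrays of one side and on at most 2 of the other. CDKN2A, the tumour suppressor gene on chromosome 9 that MCF-10A cells are known to lack, was detected on 0 of 6 control and 24 of 24 knockdown arrays, at least 15-fold higher. Its neighbour MTAP was detected on 2 of 6 and 24 of 24 arrays, at a mean log2 level of 4.78 against 10.1, and CDKN2B and ELAVL2 on 2 and 1 of 6 and 24 of 24. KLHL9 and HACD4, further genes of that region, were detected on all arrays. GSTT1, for which null alleles are common, was detected on 0 of 6 and 24 of 24 arrays (at least 14.1-fold higher). GSTM1 was detected on 6 of 6 and 1 of 24, near background at a mean log2 level of 5.39 against 4.44. Its other probes were detected on 1 and 0 of 6 control arrays. Of 7 testable genes with common null alleles, these 2 were divided in this way. Over all genes, 79 were detected on every knockdown array and no control array, and 100 on every control array and no knockdown array.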
